A study of Mus musculus with 30 samples.

How the data were processed

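RNA of sorted bone marrow progenitor populations was sequenced in 30 libraries, 3 for each of 10 groups. Per the labels, the authors trimmed reads with Trimmomatic 0.38.0, aligned them with STAR 2.7.8 to GRCm38/mm10 and counted them with featureCounts 2.0.1. The annotation release and the strand setting are not stated. The deposited table holds FPKM values made by the authors, fragments per kilobase of exon scaled to sequencing depth, for 11383 genes by symbol. The lowest mean over the 30 libraries was 1.00, so weakly expressed genes are not analysed here.

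The FPKM values were checked for the counts behind them. For 11381 of the 11383 genes (not Eef1a1 and Mpo), the values were whole numbers of reads for one exon length per gene and one total per library, within 0.02 reads or 1e-07 of the count, whichever was more, and at most 0.1 reads. This held for 0 of 200 genes with shuffled values. The totals were 23.6 to 41.3 M assigned reads per library, and the genes of the table held 96.9 to 97.9% of them. These depths give counting error only, since reads without molecular identifiers are not independent molecules. Replicates varied more than counting error alone, with a chi-square per degree of freedom between 7.43 and 63.1 over the groups, and correlated at 0.981 to 0.994 across genes, which are not independent replicates.

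Groups came from the labels. These give no sort gates, RNA quality or batch, nor say whether same-numbered libraries share a mouse or day, so no planned comparison is paired. Same-numbered LPS libraries deviated together (correlations across genes of 0.0875 to 0.404), as did naive proNeu1 and GMP-MoP, so these may share an origin.

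Each comparison used limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1), in 1 fit of all 30 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with a log2 fold change of at least 1 in size, a fold of 2. The planned filter, FPKM of at least 1 in at least 3 libraries, removed 0 genes. 10 comparisons were between naive groups, 4 between LPS and naive libraries of 1 population, and 3 tested differences of LPS effects. The interaction terms compared proNeu1 with GMP, GMP-MoP with proNeu1, and proNeu2 with proNeu1. In simulated data 97 of 100 genes changed 4-fold were called, 28 of 100 changed 2-fold, and 1 unchanged gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

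Gene lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated. The 25 lists were neutrophil primary granule; neutrophil secondary and tertiary granule; mature neutrophil; neutrophil-lineage regulators; monocyte-lineage regulators; monocyte markers; dendritic cell and MHC class II; neutrophil-like monocyte; stem and early progenitor; surface antigens often used for sorting; cell cycle; type I interferon-stimulated; interferon-gamma and GTPase; NF-kB and inflammatory; emergency granulopoiesis and STAT3; LPS sensing; glycolysis; cholesterol synthesis; unfolded protein response; ribosomal proteins; immediate early; erythroid and megakaryocyte markers; lymphoid markers; basophil, eosinophil and mast cell markers; and macrophage and stromal markers. Lists, comparisons, thresholds and the rule for named genes were fixed before the data were examined.

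Named genes were the 5 with the greatest change each way among called genes with a higher group mean of at least 10 FPKM and groups that did not overlap, without predicted genes or immunoglobulin segments. Up to 4 called members of each list and a panel of 19 lineage genes were added. For interaction terms the non-overlap condition does not apply. A few genes that this rule or the text would name are not reported here.

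Lineage position is, per library, the median over a gene set of the log2 value placed between the means of naive proNeu2 and naive cMoP. LPS and naive positions were compared by two-sided exact permutation tests, and set members among called genes by Fisher's exact test. Principal components used the 1000 most variable genes. Lengths came with the recovered counts, GC from GENCODE M21 (11208 symbols with a single gene). Shared sequence was the share of a gene's 31-base words found in another annotated gene.

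Each result was recomputed with a pseudocount of 0.1, median-of-ratios scaling, a replicate block, a fit of the compared groups alone, each library left out in turn, and no low-value filter. Chosen after seeing the data were a mean FPKM of at least 5, voom on the recovered reads, removal of length and GC trends, a replicate block within the LPS libraries, the LPS libraries numbered 2 left out, and immunoglobulin genes left out.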

Results

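The series measured RNA in sorted bone marrow progenitors of wild-type mice by RNA sequencing, in 30 libraries that fall into 10 groups of 3. 6 groups were naive: the monocyte-dendritic cell progenitor (MDP), the common monocyte progenitor (cMoP), the granulocyte-monocyte progenitor (GMP), the early committed neutrophil progenitors proNeu1 and proNeu2, and GMP-MoP, a population for which the series title names mixed neutrophil and monocyte progenitor features. 4 groups (GMP, proNeu1, proNeu2 and GMP-MoP) were labelled LPS, 2 days. LPS is lipopolysaccharide of Gram-negative bacteria, and the labels do not say how it was given. Values are FPKM for 11383 genes by symbol, given as mean ± SD of 3 libraries, first group against second. Between 23.6 and 41.3 M reads per library were assigned to genes (median 28.6 M), from 25.7 ± 1.12 M in naive MDP to 33.3 ± 6.03 M in LPS proNeu1, with the other 8 groups between. At the median depth an FPKM of 1 stands for 57.1 reads of a gene of 2000 bases. The 10 most abundant genes held 6.49 ± 0.0849% of the summed FPKM in naive cMoP and 18.9 ± 0.982% in LPS proNeu2. Among the genes followed through the series, on build GRCm38, were Irf8 on chromosome 8 (120736358 to 120756694), Csf1r on chromosome 18 (61100598 to 61132149), Gfi1 on chromosome 5 (107716657 to 107726036), Cebpe on chromosome 14 (54710360 to 54712174), Elane on chromosome 10 (79886247 to 79888215) and S100a8 on chromosome 3 (90668978 to 90670035). A gene was called higher or lower when its limma adjusted p was under 0.05 and its log2 fold change (log2FC) at least 1 in size. Log2FC values carry their standard error or stand alone in parentheses, and the leading genes of each simple comparison, named first, had 3 libraries of one group all above the 3 of the other. Gene lists were compared with the other genes by camera, and counts adjusted over the list alone were the same as those over all genes except where given.

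To see how the populations lie relative to each other, the 1000 most variable genes were reduced to principal components. The first held 56.1% of the variance and ran from naive MDP (mean -54.1) through cMoP (-35.3), GMP (-27.7), GMP-MoP (-10.1) and proNeu1 (28.99) to proNeu2 (42.7). Genes with the strongest positive weights were S100a9 and S100a8, the calprotectin subunits, with Camp, Ngp and Chil3, and those with the strongest negative weights were Irf8, Cd34 and Tpm4. The second component held 25.4% and set naive cMoP (30.5) apart from GMP (-47.7). F13a1, Ly6c2, Csf1r and Klf4 weighed on the cMoP side, and the granulocyte genes Prg2, Prss34 and Epx on the GMP side.

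**Figure D1:**
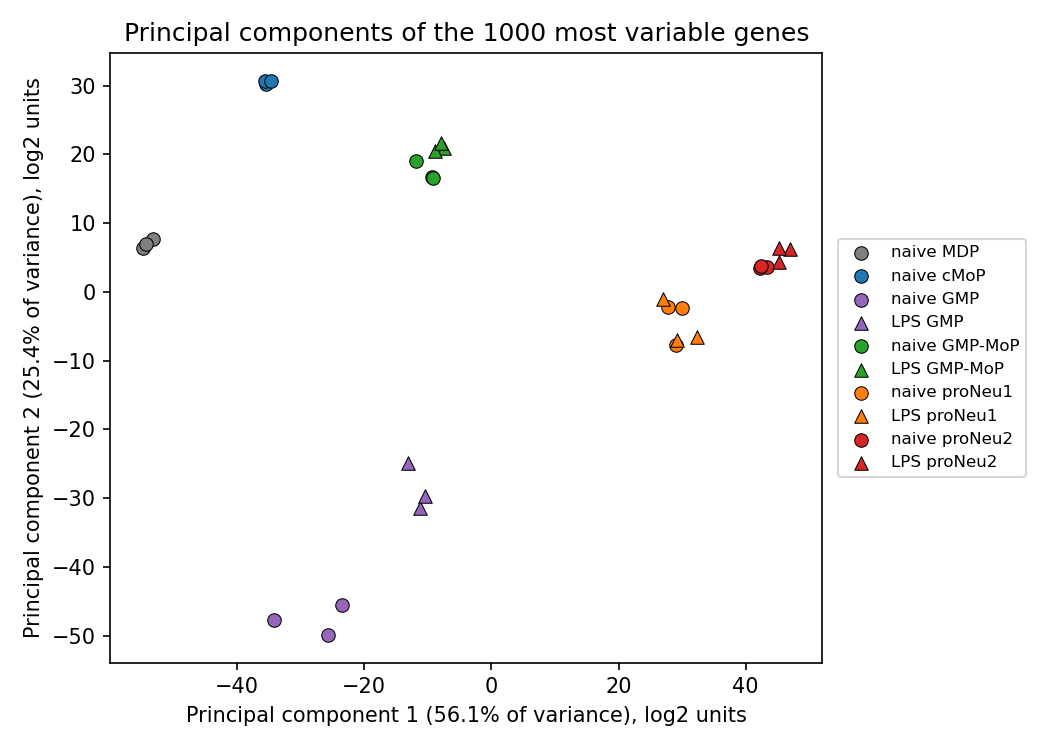
Each point is 1 library, placed by its scores on the first component (x axis, 56.1% of the variance) and the second (y axis, 25.4%), colored by group. The naive groups run from MDP on the left to proNeu2 on the right, and GMP lies apart from cMoP on the second component.

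The first question was how GMP-MoP differed from the monocyte-committed cMoP. Calprotectin genes and the neutrophil-lineage regulators Cebpe and Gfi1 were higher in GMP-MoP: S100a8 stood at 407 ± 64.3 against 8.11 ± 1.501 FPKM (log2FC 5.49 ± 0.57, adjusted p = 2.55e-08). Wfdc21 was at 19.2 ± 2.23 against 0.0750 ± 0.130 FPKM (log2FC 4.24 ± 0.26, adjusted p = 3.74e-12) and Cebpe at 39.9 ± 6.96 against 5.05 ± 0.528 FPKM (log2FC 2.75 ± 0.13, adjusted p = 2.83e-14). Gfi1 was at 32.2 ± 3.64 against 5.54 ± 0.235 FPKM (2.34). Serpine2, a protease inhibitor, was at 31.8 ± 3.52 against 1.06 ± 0.0897 FPKM (3.99). The granule enzyme gene Elane (neutrophil elastase) was at 5638 ± 402 against 1548 ± 150.3 FPKM (1.87). Mpo (myeloperoxidase) was at 5364 ± 264 against 2281 ± 122 FPKM (1.23). Monocyte genes were lower: the integrin gene Itgb7 stood at 3.32 ± 1.88 against 75.1 ± 5.86 FPKM (log2FC -4.22 ± 0.23, adjusted p = 3.45e-13), fibronectin (Fn1) at 0.728 ± 0.588 against 26.04 ± 0.610 FPKM (-4.02) and galectin Lgals3 at 6.14 ± 4.06 against 76.0 ± 3.39 FPKM (-3.57). The calcium-binding S100a6 was at 3.34 ± 2.14 against 50.4 ± 3.13 FPKM (-3.67). The monocyte transcription factors Klf4 (12.7 ± 3.32 against 71.7 ± 0.848, -2.44) and Irf8 (149 ± 20.9 against 371 ± 18.8, -1.32) and the M-CSF receptor gene Csf1r (47.0 ± 6.56 against 123 ± 5.84, -1.38) fell, whereas Ly6c2 was at 2183 ± 125 against 2228 ± 55.5 FPKM (adjusted p = 0.943).

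By list, neutrophil primary granule genes had 6 of 12 measured members higher, 0 lower and 6 not called in GMP-MoP than in cMoP (median 1.10), among them Nkg7 (3.31), Prss57 (2.67) and Ms4a3 (1.98) (camera adjusted p = 4.32e-12, adjusted p = 0.157 with an estimated correlation). Secondary and tertiary granule genes had 10 of 18 measured members higher, 1 lower and 7 not called (camera adjusted p = 1.47e-04, adjusted p = 0.394 with an estimated correlation). Neutrophil-lineage regulators were 4 higher and 4 not called of 8, with Ets1 (1.88) and Per3 (1.48) beside Cebpe and Gfi1 (camera adjusted p = 3.56e-04, adjusted p = 0.0503 with an estimated correlation). Monocyte markers were 14 lower and 4 not called of 18, median -1.68, with Ctss (-2.99) and Cx3cr1 (-2.51) among the lower (camera adjusted p = 1.11e-14, adjusted p = 0.0503 with an estimated correlation). Monocyte-lineage regulators were 3 lower and 3 not called of 6, with Irf5 (-2.07) (camera adjusted p = 0.00145, adjusted p = 0.253 with an estimated correlation). Of the progenitor genes, Kit (1.33), Cd27 (1.79) and Hlf (1.10) were higher and Flt3 (-2.19) lower. Dendritic cell and MHC class II genes were 3 lower and 9 not called of 12 (camera adjusted p = 0.00198, adjusted p = 0.356 with an estimated correlation). Over all genes, 226 were higher and 298 lower, but 439 higher and 406 lower with a pseudocount of 0.1 and 430 higher and 417 lower with voom. S100a9 (157 ± 75.2 against 1.43 ± 0.142, 5.92) was called as well, but with voom on recovered reads its adjusted p was 0.0540. Surface antigens often used for sorting were 4 higher, 3 lower and 10 not called of 17, with Vcam1 (2.75) and Cd81 (2.29) higher (camera adjusted p = 0.748; median -0.03, camera direction higher).

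Compared with the earlier MDP, GMP-MoP held granule and calprotectin transcripts at far higher levels. S100a8 was at 407 ± 64.3 against 2.57 ± 1.26 FPKM (log2FC 6.89 ± 0.57, adjusted p = 1.67e-10). Elane was at 5638 ± 402 against 128 ± 7.42 FPKM (log2FC 5.45 ± 0.15, adjusted p = 1.41e-19), while Fcnb, a ficolin gene, was at 59.8 ± 7.54 FPKM and listed at 0 in all 3 MDP libraries. Ly6c2 stood at 2183 ± 125 against 90.3 ± 1.58 FPKM (4.58). Cebpe was at 39.9 ± 6.96 against 1.09 ± 0.289 FPKM (4.28) and Lcn2 (a lipocalin) at 32.9 ± 11.5 against 0.547 ± 0.406 FPKM (4.44). Prtn3 was at 3659 ± 256.2 against 531 ± 35.5 FPKM (2.78). Among the leading lower genes was Dntt (terminal deoxynucleotidyl transferase) at 0.191 ± 0.212 against 175 ± 29.99 FPKM (log2FC -7.20 ± 0.19, adjusted p = 1.06e-19). The cytokine receptor Flt3 was at 1.45 ± 0.719 against 199 ± 8.78 FPKM (-6.39) and the invariant chain Cd74 at 0.585 ± 0.207 against 77.6 ± 25.9 FPKM (-5.59). The MHC class II gene H2-Aa was at 0.390 ± 0.266 against 56.3 ± 18.04 FPKM (-5.34). Ly6d was at 0.140 ± 0.166 against 27.4 ± 5.35 FPKM (-4.63). Irf8 fell from its MDP level (149 ± 20.9 against 454 ± 28.997, -1.61), as did Cd34 (-1.60), while Klf4 was at 12.7 ± 3.32 against 15.95 ± 4.05 FPKM (adjusted p = 0.160).

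Against MDP, 12 of 12 measured primary granule genes were higher in GMP-MoP (median 2.80), with Ms4a3 (5.21), Gstm1 (4.13) and Hp (3.67) (camera adjusted p = 1.69e-16, adjusted p = 0.0412 with an estimated correlation). Secondary and tertiary granule genes were 13 higher and 5 not called of 18 (camera adjusted p = 3.30e-08, adjusted p = 0.242 with an estimated correlation). Dendritic cell and MHC class II genes were 11 lower and 1 not called of 12, with a median of -3.62 (camera adjusted p = 4.73e-10, adjusted p = 0.0467 with an estimated correlation). Stem and early progenitor genes were 13 lower and 4 not called of 17, with Egfl7 (-2.73), Sox4 (-2.18) and Cd27 (-1.85) (camera adjusted p = 7.07e-08, adjusted p = 0.0371 with an estimated correlation). Monocyte markers went both ways, 3 higher, 4 lower and 11 not called of 18 (camera adjusted p = 0.165), with Cd14 (2.37) higher and Ctss (-2.40) and Cx3cr1 (-2.15) lower. Genes of the unfolded protein response were 7 higher and 10 not called of 17, with Sdf2l1 (1.59), Calr (1.32) and Hspa5 (1.29) (camera adjusted p = 6.45e-09, adjusted p = 0.190 with an estimated correlation). In all, 454 genes were higher and 638 lower in GMP-MoP than in MDP, but 359 higher and 271 lower at a mean FPKM of at least 5, and 522 and 529 with length and GC trends removed.

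GMP and GMP-MoP were then compared. The leading genes higher in GMP-MoP included F13a1, a coagulation factor subunit, at 255.9 ± 30.7 against 6.30 ± 0.953 FPKM (log2FC 5.14 ± 0.13, adjusted p = 2.69e-20). Ly6c2 was at 2183 ± 125 against 93.0 ± 48.0 FPKM (log2FC 4.70 ± 0.25, adjusted p = 4.24e-14) and Ly6a2 at 136 ± 17.9 against 8.66 ± 5.46 FPKM (3.99). The myeloid lectin receptor gene Clec5a was at 32.3 ± 1.13 against 1.86 ± 0.976 FPKM (3.61). Mefv, which encodes pyrin, was at 33.8 ± 2.45 against 1.92 ± 0.158 FPKM (3.57). Csf1r (47.0 ± 6.56 against 4.76 ± 0.169, 3.05), Klf4 (1.69) and Irf8 (1.46) rose, as did the granule genes Elane (5638 ± 402 against 1564 ± 456, 1.89) and Prtn3 (1.87), and Cebpe fell (39.9 ± 6.96 against 108 ± 17.9, -1.42). Genes of other granulocytes were lower, which sort composition could also give, here and in proNeu1 against GMP (untested). The basophil and mast cell protease gene Prss34 was at 0.738 ± 0.402 against 3013 ± 907 FPKM (log2FC -10.74 ± 0.32, adjusted p = 8.21e-19). The eosinophil granule gene Prg2 was at 10.9 ± 9.23 against 10146 ± 1189 FPKM (-10.36) and Epx at 0.993 ± 0.863 against 1145 ± 361 FPKM (-9.24). Ear6 was at 1.17 ± 1.02 against 642 ± 215 FPKM (-8.30), and the mast cell carboxypeptidase Cpa3 at 0.679 ± 0.426 against 683 ± 129.8 FPKM (-8.68). Mpo (5364 ± 264 against 2682 ± 415, 1.011) and S100a8 (407 ± 64.3 against 174 ± 138, 1.88) passed as well, but both calls rested on single libraries: without naive GMP replicate 1, Mpo stood at 0.88 and S100a8 at 0.70 (adjusted p = 0.0951), and without naive GMP-MoP replicate 2, Mpo was at 0.97. Chil3, a chitinase-like gene, moved from 3.01 to 1.84 without that GMP library.

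All 15 of 15 measured basophil, eosinophil and mast cell markers were lower in GMP-MoP than in GMP (median -7.22; camera adjusted p = 1.79e-18, adjusted p = 0.00925 with an estimated correlation). Erythroid and megakaryocyte markers were 9 lower and 4 not called of 13, with Pf4 (-7.34), Itga2b (-6.75) and Gata1 (-5.01) (camera adjusted p = 4.88e-07, adjusted p = 0.0555 with an estimated correlation). Lymphoid markers were 8 lower and 1 not called of 9, with Dntt (-3.21) and Cd79a (-2.57) (camera adjusted p = 3.71e-04, adjusted p = 0.144 with an estimated correlation). Macrophage and stromal markers were 7 lower and 2 not called of 9, with C1qa (-3.24) and Hmox1 (-3.19) (camera adjusted p = 6.62e-06, adjusted p = 0.0570 with an estimated correlation). Dendritic cell and MHC class II genes were 7 lower and 5 not called of 12, with Cd74 (-7.75) and H2-Aa (-7.36) (camera adjusted p = 1.70e-08, adjusted p = 0.0882 with an estimated correlation). Stem and early progenitor genes were 12 lower and 5 not called of 17, with Gata2 (-6.33) and Flt3 (-3.14) (camera adjusted p = 7.24e-11, adjusted p = 0.00925 with an estimated correlation). Monocyte markers were 7 higher, 1 lower and 10 not called of 18, with Ly86 (2.67) (camera adjusted p = 3.79e-05, adjusted p = 0.231 with an estimated correlation). Primary granule genes were 6 higher and 6 not called of 12, with Hp (2.58) and Gstm1 (1.42) (camera adjusted p = 7.77e-09, adjusted p = 0.144 with an estimated correlation). Type I interferon-stimulated genes were 6 lower and 18 not called of 24, with Irf7 (-2.46) and Ddx58 (-2.21) (camera adjusted p = 0.00110, adjusted p = 0.434 with an estimated correlation). Cholesterol synthesis genes were 4 lower and 15 not called of 19, with Cyp51 (-1.15) and Lss (-1.12) (camera adjusted p = 0.00238, adjusted p = 0.374 with an estimated correlation), but Srebf2 lost its call with trends removed. The totals were 230 higher and 743 lower, 63 of the lower ones immunoglobulin genes.

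Next, GMP-MoP was set against the neutrophil-committed proNeu1. Monocyte genes were higher in GMP-MoP, with Irf8 at 149 ± 20.9 against 5.08 ± 1.55 FPKM (log2FC 4.65 ± 0.18, adjusted p = 5.46e-16). Ly86 (an LPS co-receptor component) was at 72.0 ± 13.9 against 4.06 ± 1.03 FPKM (log2FC 3.86 ± 0.18, adjusted p = 1.67e-14) and the interferon-inducible Ifi209 at 45.7 ± 9.98 against 2.19 ± 0.601 FPKM (3.87). Ms4a6c was at 92.8 ± 20.5 against 6.86 ± 0.247 FPKM (3.56). Rasa4, a Ras GTPase activator, was at 30.4 ± 3.58 against 2.17 ± 0.471 FPKM (3.31). Klf4 (12.7 ± 3.32 against 0.422 ± 0.268, 3.26), Csf1r (47.0 ± 6.56 against 4.61 ± 0.272, 3.09) and Cd34 (2.37) were higher too. Secondary granule and calprotectin genes were lower: the cathelicidin gene Camp at 15.7 ± 7.92 against 2509 ± 299 FPKM (log2FC -7.32 ± 0.68, adjusted p = 3.18e-09). Ngp (neutrophilic granule protein) was at 43.0 ± 31.05 against 5581 ± 587 FPKM (-7.20), lactoferrin (Ltf) at 12.2 ± 9.03 against 1268 ± 164 FPKM (-6.80) and S100a9 at 157 ± 75.2 against 12841 ± 1618 FPKM (-6.44). Lcn2 was at 32.9 ± 11.5 against 1489.7 ± 199 FPKM (-5.50). Cebpe (39.9 ± 6.96 against 224 ± 18.9, -2.47) and Gfi1 (-1.62) fell, whereas Mpo was at 5364 ± 264 against 5617 ± 199 FPKM (adjusted p = 0.603). Elane was at 5638 ± 402 against 7187 ± 189.9 FPKM (adjusted p = 0.0530).

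The secondary and tertiary granule list had 17 of 18 measured members lower in GMP-MoP than in proNeu1, 0 higher and 1 not called (median -3.94; camera adjusted p = 1.66e-17, adjusted p = 0.0761 with an estimated correlation), and the mature neutrophil list 6 of 11 lower, with Ly6g (-4.05), Retnlg (-3.60) and Il1r2 (-2.73) (camera adjusted p = 1.01e-05, adjusted p = 0.0584 with an estimated correlation). Primary granule genes were 0 higher, 0 lower and 12 not called of 12, with a median of -0.48 (camera adjusted p = 2.70e-05, adjusted p = 0.329 with an estimated correlation). Neutrophil-lineage regulators were 4 lower and 4 not called of 8, with Ets1 (-2.91) and Per3 (-1.05) (camera adjusted p = 1.47e-07, adjusted p = 0.00467 with an estimated correlation). Monocyte markers were 13 higher, 1 lower and 4 not called of 18, with Ccr2 (2.98) (median 1.36; camera adjusted p = 2.22e-09, adjusted p = 0.0792 with an estimated correlation). Basophil, eosinophil and mast cell markers were 10 lower and 5 not called of 15, with Prg2 (-5.03) and Ear6 (-4.06) (camera adjusted p = 2.22e-09, adjusted p = 0.0761 with an estimated correlation). Glycolysis genes were 3 lower and 16 not called of 19: Pfkfb4 (-1.92), Slc2a3 (-1.81) and Slc16a3 (-1.63) were lower (camera adjusted p = 0.0137, adjusted p = 0.370 with an estimated correlation). Ribosomal protein genes were 0 higher, 0 lower and 38 not called of 38, with a median of 0.30 (camera adjusted p = 1.11e-05, adjusted p = 0.598 with an estimated correlation). Altogether 265 genes were higher and 384 lower.

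Against proNeu2, monocyte genes were higher in GMP-MoP and secondary granule and calprotectin genes lower. Irf8 stood at 149 ± 20.9 against 0.285 ± 0.0956 FPKM (log2FC 6.86 ± 0.18, adjusted p = 9.18e-20). Cd34 was at 98.5 ± 9.33 against 1.07 ± 0.0972 FPKM (log2FC 5.58 ± 0.10, adjusted p = 3.10e-23) and Ly86 at 72.0 ± 13.9 against 0.267 ± 0.177 FPKM (5.84). Ifi209 was at 45.7 ± 9.98 against 0.146 ± 0.101 FPKM (5.33) and Ms4a6c at 92.8 ± 20.5 against 1.62 ± 0.376 FPKM (5.15). Csf1r was at 47.0 ± 6.56 against 1.61 ± 0.381 FPKM (4.20). Camp was at 15.7 ± 7.92 against 3609.8 ± 691 FPKM (log2FC -7.83 ± 0.68, adjusted p = 3.77e-10). S100a9 was at 157 ± 75.2 against 17875 ± 2904 FPKM (-6.92) and S100a8 at 407 ± 64.3 against 16323 ± 2761 FPKM (-5.32). Ngp was at 43.0 ± 31.05 against 4768 ± 315 FPKM (-6.98). The integrin gene Itgb2l was at 0.566 ± 0.230 against 73.5 ± 3.01 FPKM (-5.58). Secondary and tertiary granule genes were 16 lower and 2 not called of 18 (camera adjusted p = 9.96e-12, adjusted p = 0.156 with an estimated correlation). Primary granule genes were 2 lower and 10 not called of 12 (median -0.56; camera adjusted p = 0.00118, adjusted p = 0.427 with an estimated correlation). Neutrophil-lineage regulators were 6 lower and 2 not called of 8, with Cebpe (-2.99), Gfi1 (-1.90) and Ets1 (-3.55) (camera adjusted p = 3.44e-06, adjusted p = 0.0140 with an estimated correlation). Neutrophil-like monocyte genes were 1 higher, 6 lower and 1 not called of 8, with Cd177 (-5.08) (camera adjusted p = 0.00312, adjusted p = 0.393 with an estimated correlation). Monocyte markers were 13 higher and 5 not called of 18, with Ccr2 (4.26) (camera adjusted p = 7.59e-07, adjusted p = 0.156 with an estimated correlation). Of the calls 832 were higher and 559 lower, so that 59.8% were higher, but with median-of-ratios scaling 631 were higher and 745 lower (45.9% higher), and with length and GC trends removed 562 and 745. That scaling moved the median of all genes from 0.15 to 0 here and in cMoP against proNeu2, and from -0.14 to -0.01 in proNeu1 against GMP.

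Turning to the monocyte branch itself, cMoP was compared with MDP. Higher in cMoP were Ly6a2 (349 ± 23.5 against 2.85 ± 0.680, log2FC 6.52 ± 0.29, adjusted p = 1.96e-15), Gda, a guanine deaminase gene (41.5 ± 1.11 against 0.647 ± 0.130, log2FC 4.69 ± 0.07, adjusted p = 5.43e-24), the IgG receptor Fcgr3 (141 ± 7.10 against 4.71 ± 0.540, 4.64), complement C3 (103 ± 0.735 against 3.17 ± 0.0897, 4.64) and Ly6c2 (2228 ± 55.5 against 90.3 ± 1.58, 4.61), with Klf4 (2.13), Cebpe (1.54) and Elane (3.58). Dntt (0.0783 ± 0.0115 against 175 ± 29.99, log2FC -7.33 ± 0.19, adjusted p = 9.95e-20), H2-Aa (0.825 ± 0.530 against 56.3 ± 18.04, -4.97), Septin1 (0.924 ± 0.461 against 49.9 ± 2.997, -4.75), Cd74 (1.92 ± 0.720 against 77.6 ± 25.9, -4.73) and Ly6d (-4.63) were lower, as were Flt3 (-4.20) and Cd34 (-1.40), and Irf8 was at 371 ± 18.8 against 454 ± 28.997 FPKM (adjusted p = 0.186). Stem and early progenitor genes were 16 lower and 1 not called of 17 (camera adjusted p = 1.59e-14, adjusted p = 0.00367 with an estimated correlation). Monocyte markers were 8 higher and 10 not called of 18, with Tgfbi (3.88), Fn1 (3.69) and Lgals3 (2.59) (camera adjusted p = 6.92e-10, adjusted p = 0.106 with an estimated correlation). LPS sensing genes were 2 higher and 12 not called of 14, with Cd14 (2.15) and Irak3 (1.15) (camera adjusted p = 0.00260, adjusted p = 0.0290 with an estimated correlation). There were 385 genes higher and 473 lower (44.9% higher), and 421 higher and 411 lower with median-of-ratios scaling (50.6%), 440 and 404 with trends removed, and 303 and 202 at a mean FPKM of at least 5.

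The committed ends of both branches were compared next. In cMoP against proNeu1, Irf8 was at 371 ± 18.8 against 5.08 ± 1.55 FPKM (log2FC 5.96 ± 0.18, adjusted p = 4.92e-19). The cathepsin gene Ctss was at 131 ± 2.50 against 1.21 ± 0.481 FPKM (log2FC 5.92 ± 0.25, adjusted p = 1.76e-16), tropomyosin Tpm4 at 116 ± 1.57 against 1.04 ± 0.296 FPKM (5.84) and Klf4 at 71.7 ± 0.848 against 0.422 ± 0.268 FPKM (5.69). Csf1r was at 123 ± 5.84 against 4.61 ± 0.272 FPKM (4.47). Lower in cMoP were S100a9 (1.43 ± 0.142 against 12841 ± 1618, log2FC -12.36 ± 0.66, adjusted p = 2.70e-14), S100a8 (8.11 ± 1.501 against 10885 ± 1431, -10.23), Ngp (0.247 ± 0.157 against 5581 ± 587, -12.13), Camp (-10.95), Ltf (-10.24), Cebpe (5.05 ± 0.528 against 224 ± 18.9, -5.22) and Gfi1 (-3.95). Monocyte markers were 16 higher and 2 not called of 18, with Ms4a6c (5.33) and Ccr2 (5.17) (camera adjusted p = 3.07e-13, adjusted p = 0.0585 with an estimated correlation). Monocyte-lineage regulators were 4 higher, 1 lower and 1 not called of 6, with Irf5 (4.35) higher and Id2 (-3.03) lower (camera adjusted p = 0.0201, adjusted p = 0.346 with an estimated correlation). Primary granule genes were 12 lower of 12 (camera adjusted p = 3.38e-11, adjusted p = 0.0906 with an estimated correlation). Secondary and tertiary granule genes were 1 higher and 17 lower of 18 (camera adjusted p = 1.70e-13, adjusted p = 0.0906 with an estimated correlation). The comparison called 713 genes higher and 711 lower (656 and 770 with median-of-ratios scaling).

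In cMoP against proNeu2, the leading genes were Irf8 (371 ± 18.8 against 0.285 ± 0.0956, log2FC 8.18 ± 0.18, adjusted p = 6.74e-22), Ly86 (173 ± 10.3 against 0.267 ± 0.177, 7.11), Ms4a6c (314 ± 9.41 against 1.62 ± 0.376, 6.92), Ifi209 (6.81) and S100a10 (276 ± 4.55 against 2.07 ± 0.358, 6.50) on the cMoP side and S100a9 (1.43 ± 0.142 against 17875 ± 2904, log2FC -12.83 ± 0.66, adjusted p = 7.92e-15), Ngp (-11.91), Camp (-11.46) and S100a8 (-10.81) on the proNeu2 side. Monocyte markers were 17 higher and 1 not called of 18 (camera adjusted p = 1.31e-10, adjusted p = 0.127 with an estimated correlation). Secondary and tertiary granule genes were 1 higher and 17 lower of 18 (camera adjusted p = 5.43e-12, adjusted p = 0.170 with an estimated correlation). Genes called higher numbered 1088 and lower 799 (57.7% higher), against 906 and 946 with median-of-ratios scaling (48.9%) and 867 and 961 with length and GC trends removed.

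Along the neutrophil branch, proNeu1 was compared with GMP. Granule and calprotectin genes were higher in proNeu1: Fcnb at 614 ± 9.79 against 5.90 ± 4.40 FPKM (log2FC 6.80 ± 0.36, adjusted p = 3.59e-14). S100a9 was at 12841 ± 1618 against 209 ± 169 FPKM (6.65) and S100a8 at 10885 ± 1431 against 174 ± 138 FPKM (log2FC 6.62 ± 0.57, adjusted p = 2.80e-10). Chil3 was at 1930.4 ± 102 against 31.6 ± 24.9 FPKM (6.54). Camp was at 2509 ± 299 against 38.2 ± 28.3 FPKM (6.50), with Ly6c2 (4.26), Gfi1 (1.91) and Elane (2.25). Cebpe (224 ± 18.9 against 108 ± 17.9, 1.06) and Mpo (5617 ± 199 against 2682 ± 415, 1.08) rose as well, but without naive GMP replicate 1 they stood at 0.92 and 0.94. Prss34 (16.9 ± 12.7 against 3013 ± 907, log2FC -7.56 ± 0.32, adjusted p = 5.83e-16), H2-Aa (1.15 ± 0.477 against 239 ± 93.9, -6.73), Cpa3 (6.73 ± 4.44 against 683 ± 129.8, -6.60) and Cd74 (-6.47) were lower. So were the protease gene Mcpt8 (21.9 ± 8.99 against 1819.7 ± 542, -6.34), Irf8 (5.08 ± 1.55 against 54.8 ± 16.2, -3.18) and Cd34 (-2.89). Of 18 secondary and tertiary granule genes, 17 were higher and 1 not called (camera adjusted p = 7.70e-15, adjusted p = 0.0821 with an estimated correlation). Primary granule genes were 11 higher and 1 not called of 12 (camera adjusted p = 3.14e-12, adjusted p = 0.0821 with an estimated correlation). Basophil, eosinophil and mast cell markers were 14 lower and 1 not called of 15, with Fcer1a (-5.99) (camera adjusted p = 1.99e-10, adjusted p = 0.0671 with an estimated correlation). Interferon-gamma and GTPase genes were 1 higher, 3 lower and 13 not called of 17, with Tgtp2 (-1.86) and Gbp2 (-1.84) (camera adjusted p = 0.00593, adjusted p = 0.218 with an estimated correlation). In total 466 genes were higher and 951 lower, 60 of the lower ones immunoglobulin genes.

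Within the neutrophil branch, proNeu2 was then compared with proNeu1. The adhesion gene Vcam1 was at 138 ± 19.1 against 24.1 ± 3.24 FPKM (log2FC 2.47 ± 0.18, adjusted p = 3.47e-10). The lectin gene Clec4b2 was at 69.2 ± 3.38 against 23.9 ± 0.966 FPKM (1.496) and Chit1 (chitotriosidase) at 23.1 ± 1.16 against 7.91 ± 1.24 FPKM (1.45). Fcnb was at 1634 ± 178 against 614 ± 9.79 FPKM (1.41). The cytokine gene Il1f9 was at 11.2 ± 1.63 against 4.51 ± 0.439 FPKM (1.14). Cd34 (1.07 ± 0.0972 against 18.3 ± 1.19, log2FC -3.22 ± 0.10, adjusted p = 2.77e-17), Plbd1 (4.12 ± 1.12 against 33.9 ± 1.46, -2.79), the ganglioside enzyme St3gal5 (1.47 ± 0.267 against 15.5 ± 2.42, -2.73), carbonic anhydrase Car1 (1.70 ± 0.270 against 15.1 ± 4.10, -2.55) and the fatty acid carrier Fabp5 (1.38 ± 0.5002 against 10.5 ± 0.427, -2.30) fell, with Irf8 (0.285 ± 0.0956 against 5.08 ± 1.55, -2.21) and Csf1r (-1.11). Monocyte markers were 8 lower and 10 not called of 18, with Ms4a6c (-1.59) and Lgals3 (-1.54) (camera adjusted p = 1.69e-04, adjusted p = 0.341 with an estimated correlation). Mature neutrophil genes were 2 lower and 9 not called of 11, or 3 lower adjusted over the list alone, with Ly6g (-2.23) (camera adjusted p = 0.915; median -0.10, camera direction higher), and Ccl6 stood at -0.91 without naive proNeu1 replicate 3. Cell cycle genes had a median of 0.29 with 0 of 31 called (camera adjusted p = 1.63e-06, adjusted p = 0.138 with an estimated correlation), and Mki67 was at 156 ± 33.0 against 103 ± 7.45 FPKM (log2FC 0.58 ± 0.14, adjusted p = 0.00227). In total 11 genes were higher and 142 lower, against 27 higher and 540 lower with a pseudocount of 0.1 and 19 and 546 with voom.

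**Figure D2:**
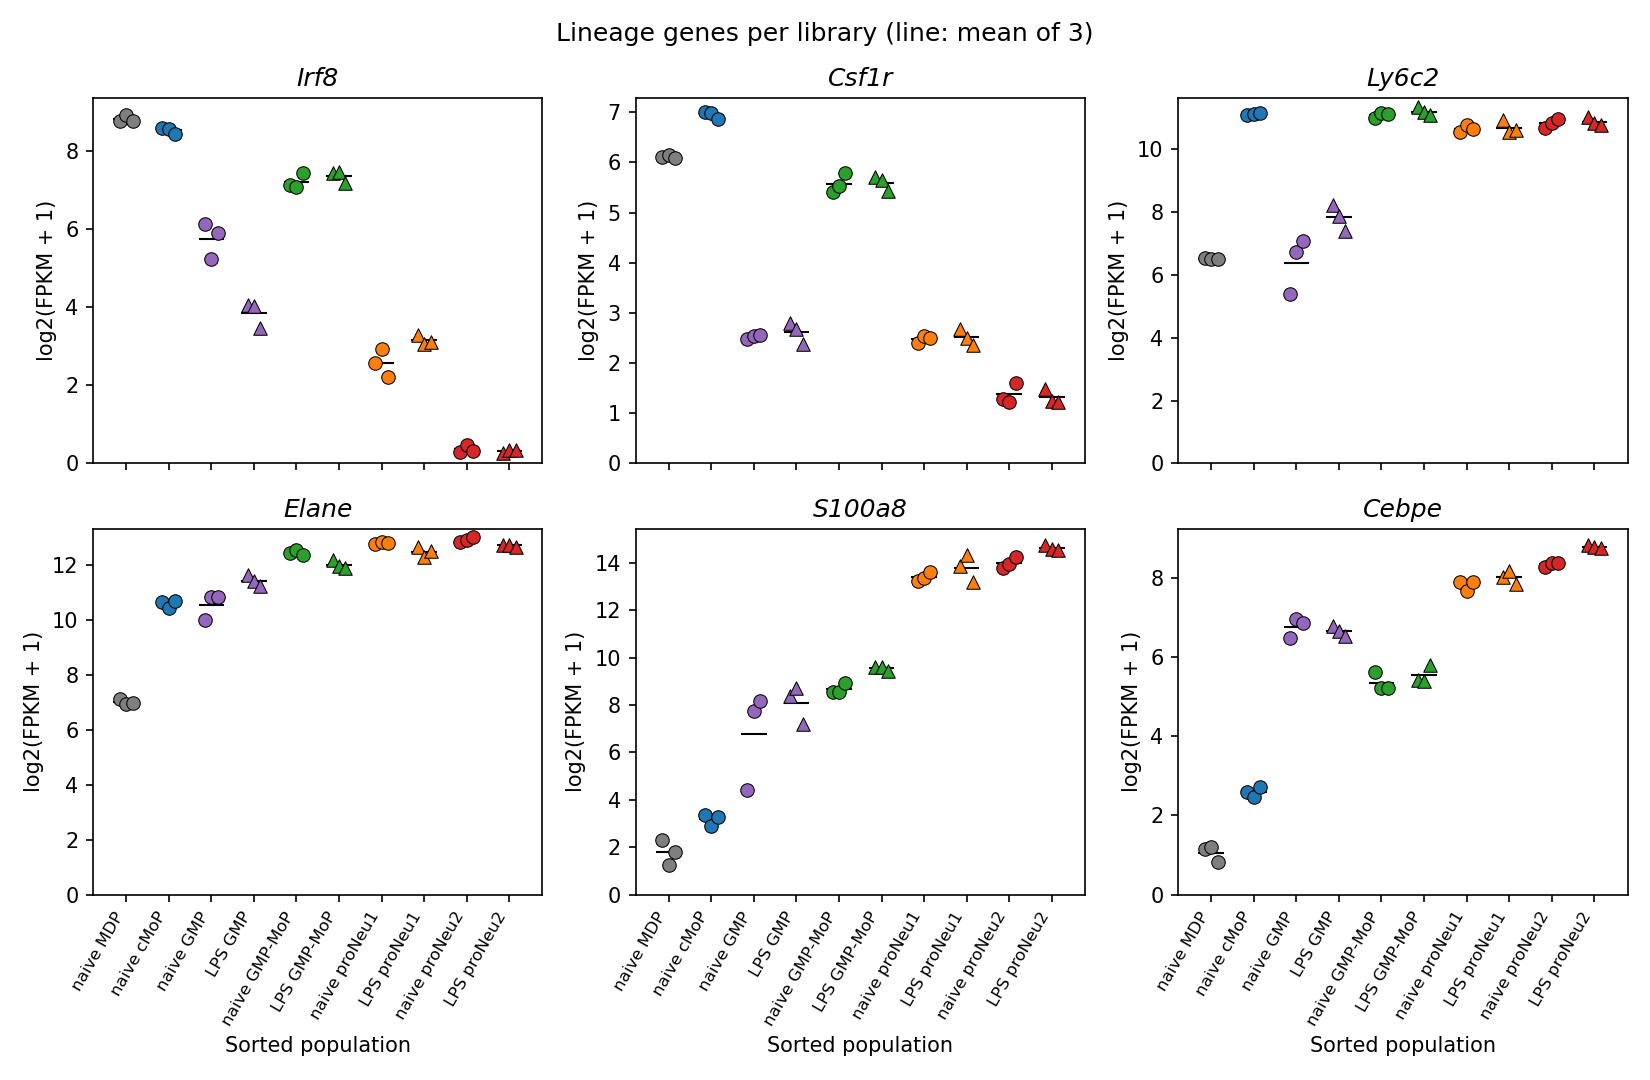
Log-scaled FPKM of Irf8, Csf1r, Ly6c2, Elane, S100a8 and Cebpe in the 10 groups. Points are libraries and bars mark group means. Irf8 had a mean FPKM of 371 in naive cMoP, 149 in naive GMP-MoP and 5.08 in naive proNeu1, and Cebpe 5.05, 39.9 and 224.

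To place GMP-MoP between the monocyte and neutrophil branches, 667 genes higher in naive cMoP than in both proNeu groups formed a monocyte-progenitor set, and 617 genes higher in both proNeu groups than in cMoP a neutrophil-progenitor set. Both sets were chosen on these samples and are not independent evidence of their direction. A library's position on each set is the median over its genes of the share of the way from naive proNeu2 (0) to naive cMoP (1). Naive GMP-MoP lay at 0.588 ± 0.0547 on the monocyte set and 0.649 ± 0.00854 on the neutrophil set, naive GMP at 0.609 ± 0.0411 and 0.617 ± 0.0631, naive MDP at 0.931 ± 0.0195 and 1.003 ± 0.00323, and naive proNeu1 at 0.154 ± 0.00840 and 0.132 ± 0.00849. Between GMP-MoP and GMP, members of both sets were over-represented in both directions (two-sided Fisher's exact test against all other genes): 78 of the 667 monocyte genes were higher (adjusted p = 9.15e-39) and 93 lower (2.03e-12), and 56 of the 617 neutrophil genes higher (9.14e-22) and 114 lower (7.86e-25). In GMP with LPS, 97 monocyte genes were lower (adjusted p = 5.97e-40) and 6 higher (adjusted p = 1), while 32 neutrophil genes were higher (5.41e-16) and 29 lower (0.0251). In GMP-MoP with LPS, 26 monocyte genes were higher (adjusted p = 8.40e-13) and 2 lower (adjusted p = 1), and 10 neutrophil genes were higher (0.0172) and 14 lower (1.58e-07), over 12 such tests. These p-values take genes as independent, which they are not, and do not measure library spread. Genes chosen to differ may also be called more often both ways. The proNeu groups took part in choosing the sets, so their counts were not tested. In proNeu1, LPS went with 20 monocyte genes higher (3.00% of the set, against 0.905% of the other genes) and 2 lower, and with 6 neutrophil genes higher (0.972% against 1.03%) and 24 lower (3.89% against 0.242%). In proNeu2 it went with 11 monocyte genes higher (1.65% against 0.467%) and 0 lower, and with 12 neutrophil genes higher (1.94% against 0.455%) and 17 lower (2.76% against 0.325%).

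The position of LPS GMP on the monocyte set was 0.410 ± 0.0228, a difference of -0.198 from naive GMP (two-sided exact permutation p = 0.1), and that of LPS GMP-MoP was 0.640 ± 0.0246, a difference of 0.0523 (exact permutation p = 0.2). On the neutrophil set the differences were -0.0839 in GMP (exact permutation p = 0.2) and 0.0327 in GMP-MoP (exact permutation p = 0.3). For proNeu1 they were 0.0118 and 0.0328 (exact permutation p = 0.2 for each), and for proNeu2 -0.00184 (exact permutation p = 0.4) and 0.00283 (exact permutation p = 1). With 3 libraries against 3 the smallest possible p is 0.1, and the lowest adjusted value over the 8 tests was 0.32, so none passed. The GMP-MoP difference on the monocyte set was 0.0327 without naive GMP-MoP replicate 2, 0.0835 without naive GMP-MoP replicate 3, and 0.00824 with sets chosen from cMoP against proNeu2 alone, with which that of proNeu1 became -0.0288. On the neutrophil set, GMP stood at -0.0479 without naive GMP replicate 1, GMP-MoP at 0.0173 without LPS GMP-MoP replicate 2 and proNeu1 at 0.0105 without LPS proNeu1 replicate 3; median-of-ratios scaling gave 0.0152 in GMP-MoP and 0.00932 in proNeu1. Over the runs with 1 library left out, proNeu1 ranged from 0.00576 to 0.0177 on the monocyte set, and proNeu2 from -0.00257 to -5.04e-04 on it and from -0.00515 to 0.0174 on the neutrophil set.

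**Figure D3:**
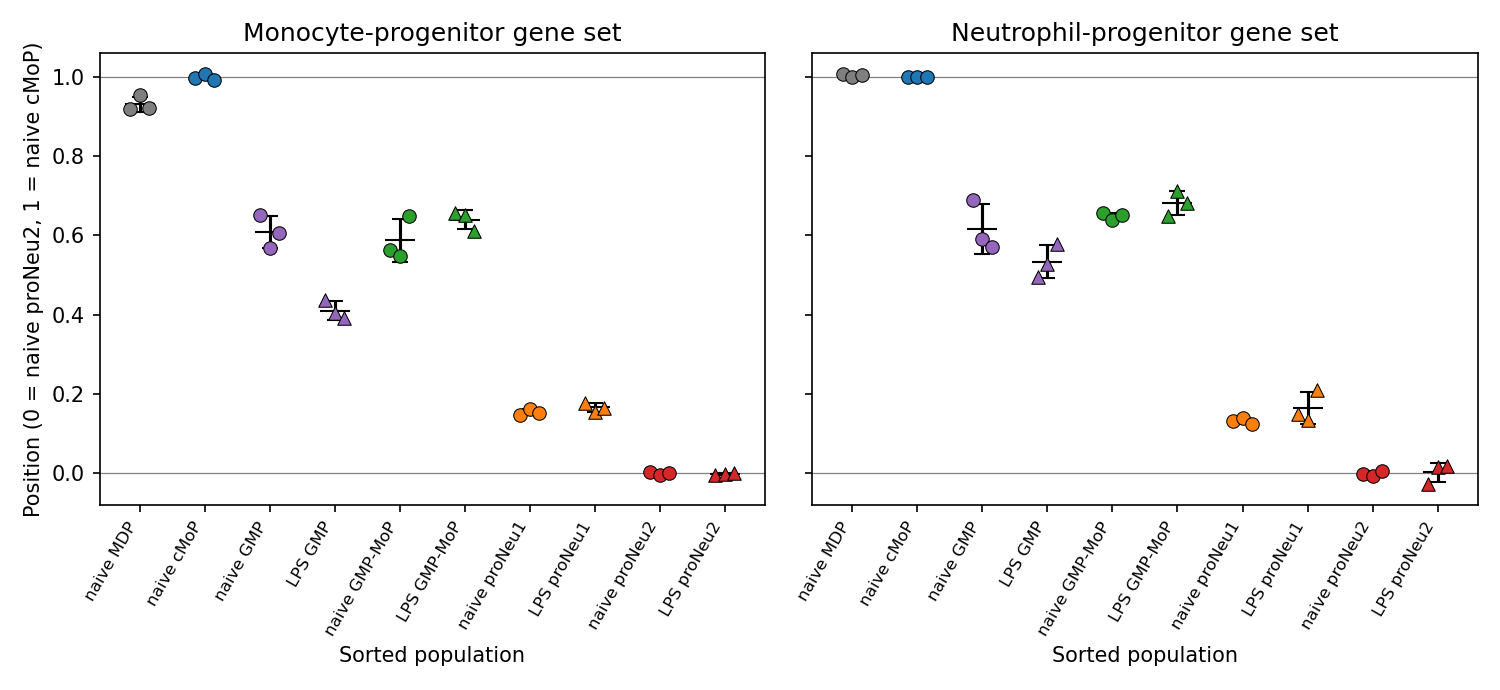
Position of each library (points) and group mean with SD (bars) on the monocyte-progenitor set and the neutrophil-progenitor set, where 0 is naive proNeu2 and 1 naive cMoP. On the monocyte set naive GMP lies at 0.609 and LPS GMP at 0.410, and GMP-MoP at 0.588 naive and 0.640 with LPS, a difference of 0.00824 with sets chosen from cMoP against proNeu2 alone.

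The second question was how each population differed 2 days after LPS. In GMP, the whey-acidic-protein family gene Wfdc21 was at 54.4 ± 4.70 against 6.55 ± 3.91 FPKM (log2FC 3.06 ± 0.26, adjusted p = 2.29e-09). Clec5a was at 16.1 ± 2.63 against 1.86 ± 0.976 FPKM (log2FC 2.63 ± 0.16, adjusted p = 5.15e-12) and F13a1 at 40.0 ± 8.47 against 6.30 ± 0.953 FPKM (2.47). The short RNA Bc1 was at 22.4 ± 15.5 against 1.96 ± 0.319 FPKM (2.76). Fcor was at 12.6 ± 0.869 against 1.995 ± 1.85 FPKM (2.40), and the granule protease gene Prtn3 rose (3411 ± 235 against 1026 ± 278, 1.77). Megakaryocyte and erythroid genes fell: platelet factor Pf4 to 11.5 ± 5.03 against 206 ± 11.3 FPKM (log2FC -4.13 ± 0.23, adjusted p = 1.19e-12). Car1 fell to 2.18 ± 0.809 against 45.9 ± 7.61 FPKM (-3.90) and the urea transporter Slc14a1 to 1.84 ± 0.786 against 34.8 ± 5.14 FPKM (-3.69). The water channel Aqp1 fell to 1.21 ± 0.319 against 23.2 ± 3.44 FPKM (-3.45). H2-Aa fell too (22.4 ± 10.8 against 239 ± 93.9, -3.40). Irf8 (13.7 ± 3.10 against 54.8 ± 16.2, -1.90), Klf4 (0.403 ± 0.112 against 3.28 ± 1.17, -1.57) and Flt3 (-1.86) were lower, whereas Csf1r was at 5.21 ± 0.904 against 4.76 ± 0.169 FPKM (adjusted p = 0.491). Elane was at 2793 ± 371 against 1564 ± 456 FPKM (log2FC 0.88 ± 0.15, adjusted p = 3.74e-05). Gfi1 (58.7 ± 2.89 against 26.6 ± 7.10, 1.15), Ly6c2 (235 ± 65.8 against 93.0 ± 48.0, 1.45) and Lcn2 (79.4 ± 21.3 against 39.3 ± 25.4, 1.26) passed, but without naive GMP replicate 1 they stood at 0.91, 0.95 and 0.54 (adjusted p = 0.155 for Lcn2, and 0.0552 without LPS GMP replicate 2).

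The lists were then counted in GMP with LPS. Monocyte-lineage regulators were 4 lower and 2 not called of 6, with Id2 (-2.07) and Irf5 (-1.69) (camera adjusted p = 0.00960, adjusted p = 0.221 with an estimated correlation). Of 12 dendritic cell and MHC class II genes, 8 were lower and 4 not called, with Cd74 (-3.38) and H2-Ab1 (-2.68) (camera adjusted p = 4.62e-08, adjusted p = 0.116 with an estimated correlation). Erythroid and megakaryocyte markers were 9 lower and 4 not called of 13, with Vwf (-3.00) and Gp9 (-2.20) (median -1.59; camera adjusted p = 3.70e-06, adjusted p = 0.116 with an estimated correlation). Lymphoid markers were 7 lower and 2 not called of 9, with Dntt (-2.66) and Cd79a (-2.50) (median -1.62; camera adjusted p = 3.38e-04, adjusted p = 0.132 with an estimated correlation). Basophil, eosinophil and mast cell markers were 7 lower and 8 not called of 15 (median -0.98; camera adjusted p = 2.60e-04, adjusted p = 0.221 with an estimated correlation). Macrophage and stromal markers were 6 lower and 3 not called of 9, with Hmox1 (-1.90) and C1qb (-1.42) (camera adjusted p = 5.31e-05, adjusted p = 0.116 with an estimated correlation). Of 17 stem and early progenitor genes, 1 was higher, 5 lower and 11 not called, with Mycn (-2.81) lower (camera adjusted p = 1.85e-04, adjusted p = 0.118 with an estimated correlation). Of 12 primary granule genes, 4 were higher and 8 not called, with Hp (1.57) and Gstm1 (1.27) (camera adjusted p = 6.03e-09, adjusted p = 0.118 with an estimated correlation). Emergency granulopoiesis and STAT3 genes were 3 higher and 8 not called of 11, with Lrg1 (2.13) and Cebpb (1.504) (camera adjusted p = 1.85e-04, adjusted p = 0.116 with an estimated correlation). Cell cycle genes were 0 higher, 0 lower and 31 not called of 31, with a median of 0.28 (camera adjusted p = 3.70e-06, adjusted p = 0.118 with an estimated correlation). Mki67 was at 57.5 ± 3.44 against 73.9 ± 14.9 FPKM (log2FC -0.34 ± 0.14, adjusted p = 0.0431). Counted over all genes, 104 were higher and 346 lower, 39 of the lower ones immunoglobulin genes.

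In GMP-MoP with LPS, the interferon-inducible membrane protein gene Ifitm1 was at 75.9 ± 21.8 against 5.21 ± 1.17 FPKM (log2FC 3.60 ± 0.34, adjusted p = 7.55e-08). The lysosomal thiol reductase gene Ifi30 was at 33.0 ± 7.69 against 6.98 ± 2.13 FPKM (log2FC 2.10 ± 0.15, adjusted p = 9.24e-10) and Wfdc21 at 101 ± 11.1 against 19.2 ± 2.23 FPKM (2.33). Lcn2 was at 124 ± 16.7 against 32.9 ± 11.5 FPKM (1.92). Bc1 was at 21.7 ± 6.73 against 3.51 ± 2.82 FPKM (2.47). The stem cell antigen gene Ly6a (2.47), serum amyloid Saa3 (1.70) and the transcription factor Cebpb (1.48) rose as well. Dusp6, a MAP kinase phosphatase gene, fell (1.85 ± 0.993 against 10.4 ± 3.92, log2FC -2.00 ± 0.22, adjusted p = 6.08e-07), as did the adenylate kinase Ak4 (3.36 ± 0.659 against 12.5 ± 1.65, -1.63), the sulfotransferase Chst13 (5.41 ± 0.117 against 17.96 ± 1.69, -1.56), the ubiquitin ligase Nedd4 (9.86 ± 1.51 against 26.98 ± 1.51, -1.37) and Cd34 (43.7 ± 6.45 against 98.5 ± 9.33, -1.16). Irf8 was at 166 ± 17.1 against 149 ± 20.9 FPKM (adjusted p = 0.543). Cebpe was at 45.7 ± 7.61 against 39.9 ± 6.96 FPKM (adjusted p = 0.274) and Klf4 at 23.9 ± 4.05 against 12.7 ± 3.32 FPKM (log2FC 0.88 ± 0.18, adjusted p = 8.46e-04). Kit was at 37.5 ± 3.52 against 67.4 ± 1.84 FPKM (log2FC -0.83 ± 0.08, adjusted p = 1.16e-07). Emergency granulopoiesis and STAT3 genes were 2 higher and 9 not called of 11, with Lrg1 (1.26) (camera adjusted p = 7.87e-04, adjusted p = 0.228 with an estimated correlation). Type I interferon-stimulated genes were 3 higher and 21 not called of 24 (median 0.52; camera adjusted p = 1.52e-05, adjusted p = 0.488 with an estimated correlation). Monocyte markers were 4 higher and 14 not called of 18 (median 0.29; camera adjusted p = 3.76e-05, adjusted p = 0.488 with an estimated correlation). The called members lay close to the fold threshold: Oas1a (1.05), Oasl1 (1.004), Ifi27l2a (1.05), Lgals3 (1.26), Ccr2 (1.02), Ms4a6b (1.013) and Ctss (1.009). Calls were lost without LPS GMP-MoP replicate 3 (Oas1a 0.83, Oasl1 0.74, Ifi27l2a 0.60, Ms4a6b 0.99), replicate 1 (Ccr2 0.93, Ms4a6b 0.98) and replicate 2 (Ctss 0.92), and without naive GMP-MoP replicate 1 (Oasl1 0.98, Ccr2 0.95, Ms4a6b 0.95, Ctss 0.83), replicate 2 (Ifi27l2a 0.86, Lgals3 0.97, Ccr2 0.88, Ctss 0.80) and replicate 3 (Oasl1 0.998, Ifi27l2a at adjusted p = 0.0705). Of 12 primary granule genes, 0 were higher, 0 lower and 12 not called (camera adjusted p = 0.561; median -0.03, or 0.01 with median-of-ratios scaling, camera direction higher). Immediate early genes were 0 higher, 0 lower and 8 not called of 8 (camera adjusted p = 0.341; median -0.50). In sum 82 genes were higher and 47 lower.

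In proNeu1 with LPS, Ifitm1 was at 32.8 ± 13.7 against 2.08 ± 0.730 FPKM (log2FC 3.38 ± 0.34, adjusted p = 2.40e-07). The antibody joining chain gene Jchain was at 44.5 ± 22.03 against 6.04 ± 4.48 FPKM (log2FC 2.74 ± 0.42, adjusted p = 3.72e-05) and Bc1 at 16.03 ± 4.85 against 2.53 ± 0.393 FPKM (2.23). The lipase gene Lipg was at 13.6 ± 7.13 against 2.28 ± 0.257 FPKM (1.99) and clusterin (Clu) at 12.2 ± 2.39 against 2.52 ± 0.340 FPKM (1.90), and Saa3 (2.09), Ly6a (1.84) and Cebpb (1.17) rose. Of the 117 genes called higher, 59 were immunoglobulin genes, including Ighm (347 ± 168 against 99.4 ± 52.1, 1.76); the 73 measured ones had a median of 2.04. Igkc, an antibody light chain gene, lay between 176 and 661 FPKM in the 3 LPS proNeu1 libraries, between 20.5 and 125 in the naive ones and between 370.0 and 731 in naive GMP. Lower were Car1 (2.41 ± 0.476 against 15.1 ± 4.10, log2FC -2.22 ± 0.22, adjusted p = 1.69e-07), Macrod1 (4.75 ± 0.506 against 17.6 ± 3.06, -1.68), Apoe (5.67 ± 0.398 against 17.9 ± 2.60, -1.50), the lipoxygenase Alox15 (3.07 ± 0.476 against 10.4 ± 1.29, -1.48) and Cd34 (7.94 ± 1.44 against 18.3 ± 1.19, -1.12), the last at -0.99 without LPS proNeu1 replicate 2. Elane was at 5816 ± 758 against 7187 ± 189.9 FPKM (adjusted p = 0.117). S100a8 was at 14888 ± 5637 against 10885 ± 1431 FPKM (adjusted p = 0.645). Irf8 was at 7.93 ± 0.748 against 5.08 ± 1.55 FPKM (log2FC 0.58 ± 0.18, adjusted p = 0.0159). Basophil, eosinophil and mast cell markers were 6 lower and 9 not called of 15, or 7 lower adjusted over the list alone (median -0.90; camera adjusted p = 7.49e-04, adjusted p = 0.441 with an estimated correlation). Without naive proNeu1 replicate 3, Epx (-0.85), Gata2 (-0.94), Prg3 (-0.71) and Ear1 (adjusted p = 0.0587) lost their calls, and a pseudocount of 0.1 ended those of Epx (0.0677), Ear1 (0.147) and Ear6 (0.0992). Erythroid and megakaryocyte markers were 2 lower and 11 not called of 13 (camera adjusted p = 7.49e-04, adjusted p = 0.384 with an estimated correlation), with Itga2b at -0.96 and -0.99 without naive or LPS proNeu1 replicate 3. Type I interferon-stimulated genes had a median of 0.33 with 1 of 24 higher, Ifi27l2a at 1.06 (camera adjusted p = 7.49e-04, adjusted p = 0.562 with an estimated correlation), a call lost without naive proNeu1 replicate 1 (adjusted p = 0.0821) or 3 (0.0762) and without LPS proNeu1 replicate 2 (0.130) or 3 (0.128). Beside the 117 higher genes 50 were lower, and without the immunoglobulin genes 58 were higher and 50 lower. With a pseudocount of 0.1, 179 were higher and 180 lower, and with voom 168 higher and 206 lower.

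In proNeu2 with LPS, Ifitm3 was at 106 ± 49.2 against 13.9 ± 3.73 FPKM (log2FC 2.76 ± 0.26, adjusted p = 5.29e-08). Lipg was at 51.9 ± 21.6 against 7.44 ± 2.15 FPKM (log2FC 2.57 ± 0.32, adjusted p = 1.49e-06) and Clu at 11.6 ± 2.27 against 2.28 ± 0.348 FPKM (1.93). Ifitm6 was at 93.2 ± 21.4 against 26.7 ± 1.30 FPKM (1.74), the linker histone gene H1f2 at 34.3 ± 4.57 against 11.6 ± 0.896 FPKM (1.47), and Saa3 (2.84), Cebpb (1.32), Oas2 (1.49) and the decoy receptor Il1r2 (1.27) rose. Kit, the stem cell factor receptor gene, fell (25.2 ± 3.53 against 59.3 ± 2.97, log2FC -1.21 ± 0.08, adjusted p = 3.07e-10), with Dnph1 (4.75 ± 0.611 against 11.5 ± 1.47, -1.12) and the microRNA gene Mir3113 (5.63 ± 2.696 against 16.1 ± 1.97, -1.44). The amino acid transporter Slc7a5 (9.42 ± 2.86 against 21.2 ± 0.414, -1.13) was at -0.88 without LPS proNeu2 replicate 1, and the transferrin receptor Tfrc (39.4 ± 4.603 against 86.2 ± 6.44, -1.11) at -0.97 with length and GC trends removed. Cebpe was at 439 ± 11.6 against 322 ± 11.6 FPKM (log2FC 0.45 ± 0.13, adjusted p = 0.00923). Elane was at 6761 ± 188 against 7819 ± 433 FPKM (adjusted p = 0.283). Type I interferon-stimulated genes were 2 higher and 22 not called of 24 (camera adjusted p = 5.25e-05, adjusted p = 0.761 with an estimated correlation), with Oas1a at 0.999 without naive proNeu2 replicate 1 and 0.87 without LPS proNeu2 replicate 3. Emergency granulopoiesis and STAT3 genes were 1 higher and 10 not called of 11 (camera adjusted p = 8.21e-05, adjusted p = 0.0933 with an estimated correlation). In the NF-kB and inflammatory list Saa3 alone passed, 1 higher and 12 not called of 13 (camera adjusted p = 0.0898). In this comparison 61 genes were higher and 52 lower (54.0% higher), and 88 higher and 42 lower with median-of-ratios scaling (67.7%). Most calls were lower with a pseudocount of 0.1 (151 higher and 240 lower), with voom (155 higher and 259 lower) and without naive proNeu2 replicate 2 (59 higher and 67 lower).

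**Figure D4:**
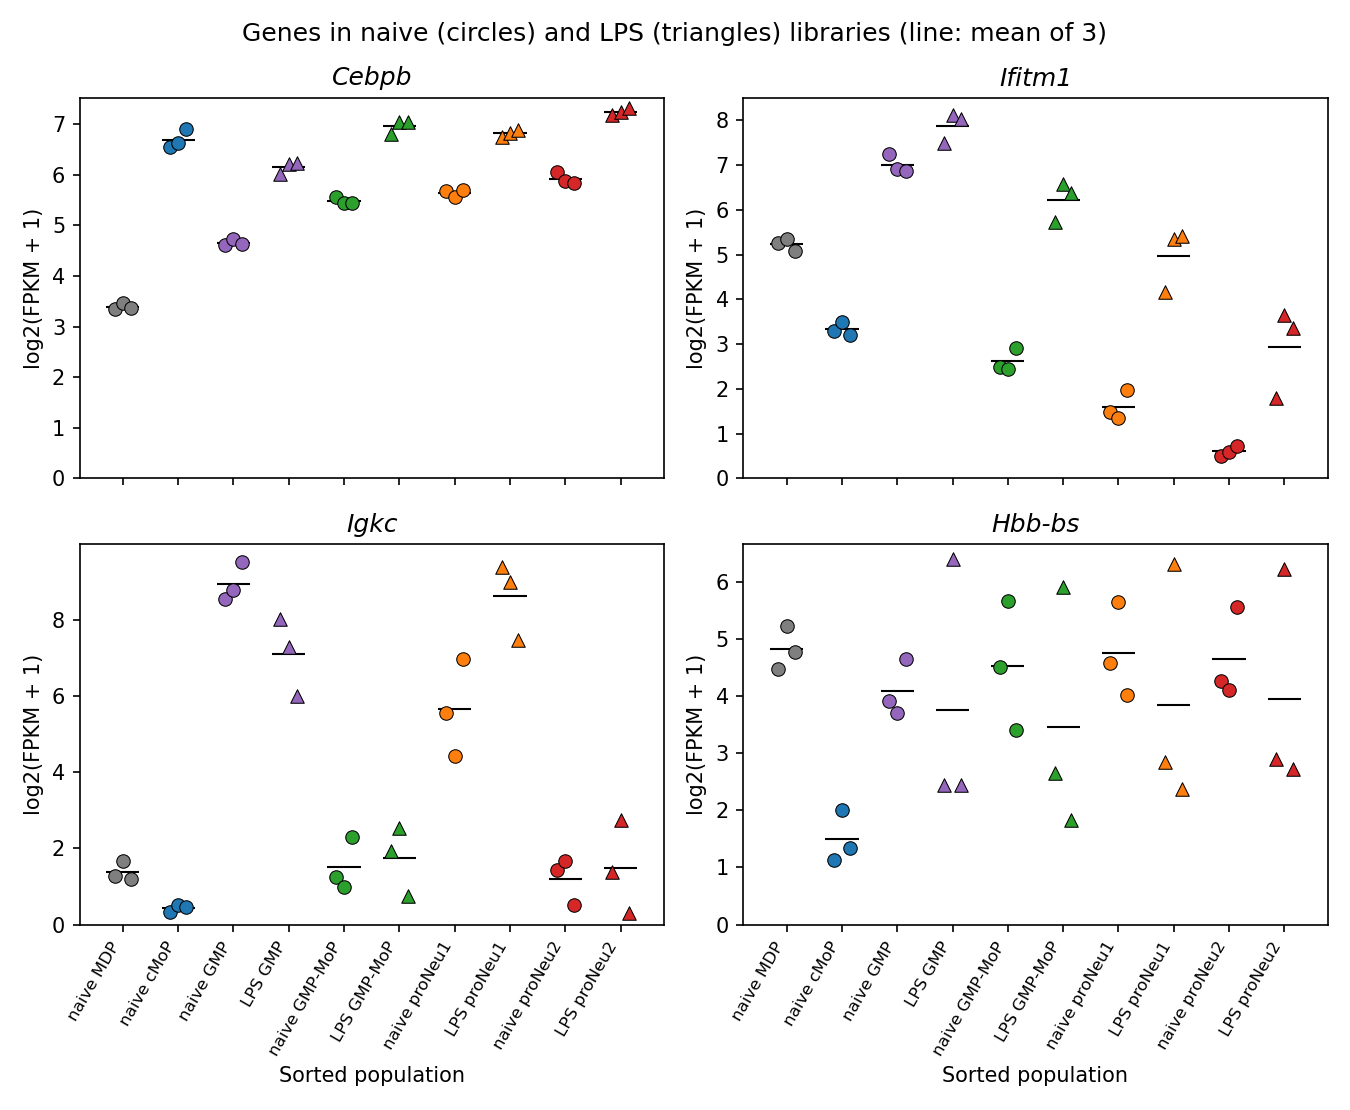
Log-scaled FPKM of Cebpb, Ifitm1, Igkc and Hbb-bs by group. Points are libraries and bars mark group means. Igkc spans 370.0 to 731 in naive GMP and 176 to 661 in LPS proNeu1.

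The LPS comparisons shared genes. LPS GMP-MoP and LPS proNeu1 had 28 higher genes in common, where independent lists of those sizes would share 0.843, LPS proNeu1 and LPS proNeu2 31 (0.627), and LPS GMP and LPS GMP-MoP 23 (0.749). These expected counts ignore that same-numbered LPS libraries deviated together. The lower genes shared were 16, 14 and 7. LPS GMP and LPS proNeu1 shared 19 higher genes, and 36, mostly immunoglobulin genes, were lower in GMP and higher in proNeu1. 24 genes were higher in at least 3 of the 4 comparisons and 12 in all 4. With log2 fold changes in the order GMP, GMP-MoP, proNeu1 and proNeu2, these 12 included the transcription factor Cebpb (1.504, 1.48, 1.17 and 1.32), the metallothionein Mt1 (2.17, 1.16, 1.29 and 1.02), the chaperone Clu (1.33, 1.13, 1.90 and 1.93), the apoptosis regulator Pmaip1 (1.55, 1.77, 2.14 and 1.57), Bc1 (2.76, 2.47, 2.23 and 1.92) and Tomm7 (1.24, 1.20, 1.14 and 1.09). These examples were chosen after their values were seen. Lower in 3 comparisons were 11 genes, among them Dusp6 (-0.71, -2.00, -1.44 and -1.39), Thbs1 (-1.53, -1.54, -2.19 and -1.84) and Ak4 (0.62, -1.63, -1.29 and -1.48). Of the 24 shared higher genes, 15 had over 10% of their sequence words in common with other genes (42.9% for Bc1), against 16.7% of all genes, and 7 had under 1%, Cebpb, Clu, Mt1 and Pmaip1 among them. Across genes, which are not independent replicates, the log2 fold change fell with gene length in all 4 comparisons (Spearman's rho -0.25, -0.28, -0.30 and -0.28). The hemoglobin gene Hbb-bs stood at 83.5, 59.3, 79.1 and 74.1 FPKM in replicate 2 of LPS GMP, GMP-MoP, proNeu1 and proNeu2, against 2.54 to 6.45 FPKM in the other 8 LPS libraries.

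Whether the LPS difference itself varied between populations was tested with 3 interaction terms. Between proNeu1 and GMP, the LPS log2 fold change was greater in proNeu1 for Jchain (difference 4.74 ± 0.59, adjusted p = 3.10e-06), Ighm (3.85), Cd74 (difference 3.81 ± 0.50, adjusted p = 7.47e-06), H2-Aa (3.45), Pf4 (3.27), Irf8 (difference 2.48 ± 0.25, adjusted p = 1.87e-07), Klf4 (1.84) and Flt3 (2.11). These were Clec5a (difference -2.37 ± 0.22, adjusted p = 6.46e-08), Wfdc21 (-2.27), the receptor gene Trem3 (-1.95), Ak4 (-1.91), Prom1 (-1.86) and Prtn3 (-1.43), and Elane (-1.19) and Ly6c2 (-1.42), which stood at -0.92 and -0.91 without naive GMP replicate 1. Of 12 dendritic cell and MHC class II genes, 7 were positive and 5 not called (camera adjusted p = 3.54e-08). Monocyte-lineage regulators were 4 positive and 2 not called of 6, with Id2 (2.62) and Irf5 (1.90) (camera adjusted p = 3.77e-04). Lymphoid markers were 7 positive and 2 not called of 9 (camera adjusted p = 3.94e-06). Of 12 primary granule genes, 3 were negative and 9 not called, with Hp (-1.32) (camera adjusted p = 2.79e-10). With an estimated correlation, camera gave adjusted p = 0.113 for each of these lists. Monocyte markers were 8 positive, 2 negative and 8 not called of 18, or 3 negative adjusted over the list alone, with Ctss (2.96) and Mpeg1 (2.09) (camera adjusted p = 5.23e-04, adjusted p = 0.322 with an estimated correlation). This term was positive for 325 genes, 63 of them immunoglobulin genes, and negative for 58.

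Between GMP-MoP and proNeu1 the term was positive for 7 genes and negative for 18, 14 of the latter immunoglobulin genes, and without those genes in the fit 6 were positive and 4 negative. In place of 25 genes, 43 were called without LPS proNeu1 replicate 2 (25 positive and 18 negative) and 40 without LPS proNeu1 replicate 3 (6 and 34). Without naive GMP-MoP replicate 3, 17 were positive and 15 negative, and without the LPS libraries numbered 2, 16 and 16. With a replicate block within the LPS libraries, whose same-numbered members deviated together, 10 were positive and 31 negative. Car1 (difference 2.09 ± 0.31, adjusted p = 7.89e-04), Alox15 (1.45) and Ifi30 (1.24) were positive, but with voom on recovered reads their adjusted p was 0.234, 0.570 and 0.234; the membrane protein gene Plp2 (difference 1.21 ± 0.22, adjusted p = 0.00444) was positive too, with an adjusted p of 0.127 when the other groups were left out of the fit. The chemokine Ccl6 (difference 1.08 ± 0.24, adjusted p = 0.0427) lost its call without any 1 of 9 libraries, all but naive proNeu1 replicate 1, naive GMP-MoP replicate 3 and LPS proNeu1 replicate 2 (adjusted p from 0.0593 to 0.132). Milr1 (difference -1.01 ± 0.14, adjusted p = 4.91e-04), an inhibitory receptor gene, lay between -0.999 and -0.86 without naive proNeu1 replicate 1 or 3, naive GMP-MoP replicate 3, LPS proNeu1 replicate 2, or LPS GMP-MoP replicate 1 or 3. Aqp1 (1.61), Tubb2a (1.20), Fah (-1.45), Stfa1 (-1.47) and Rbpms (-1.14) were called as well, named here after their values were seen. Of 18 secondary and tertiary granule genes, 0 were positive, 0 negative and 18 not called, or 2 positive adjusted over the list alone (camera adjusted p = 6.57e-04, adjusted p = 0.935 with an estimated correlation). Of 13 erythroid and megakaryocyte markers, 1 was positive and 12 not called, or 3 positive by that count (camera adjusted p = 9.65e-08, adjusted p = 0.0806 with an estimated correlation). Of 15 basophil, eosinophil and mast cell markers, 0 were positive, 0 negative and 15 not called, or 6 positive by that count (camera adjusted p = 6.82e-05, adjusted p = 0.664 with an estimated correlation). The terms of Irf8 (difference -0.43 ± 0.25, adjusted p = 0.774), Cebpe (adjusted p = 0.998) and Cd34 (adjusted p = 0.994) did not pass.

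Between proNeu2 and proNeu1 the term was positive for 4 genes and negative for 14, 12 of the latter immunoglobulin genes, and without those genes in the fit 4 were positive and 1 negative. In place of 18 genes, 30 and 32 were called without LPS proNeu1 replicate 2 (13 positive and 17 negative) and 3 (2 and 30), and 5 positive and 29 negative with the LPS replicate block. Slc2a3 (difference 1.18 ± 0.22, adjusted p = 0.00904) stood at 0.97 without LPS proNeu1 replicate 3, and at an adjusted p of 0.193 when the other groups were left out of the fit. Car1 (difference 1.49 ± 0.31, adjusted p = 0.0246) lost its call without any 1 of 8 libraries, all but naive proNeu1 replicate 1, naive proNeu2 replicate 3, and replicate 2 of LPS proNeu1 and of LPS proNeu2 (adjusted p from 0.0572 to 0.0906), and Jchain (difference -2.68 ± 0.59, adjusted p = 0.0460) without any 1 of 9, all but naive and LPS proNeu1 replicate 3 and LPS proNeu2 replicate 2 (adjusted p from 0.0692 to 0.142). The Jchain call was also lost with the replicate block (adjusted p = 0.0601) and 6 other alternatives (0.0508 to 0.912, the highest with voom), and that of Car1 with a pseudocount of 0.1 (0.385) and voom (0.704). Aqp1 (1.48), Nrgn (1.30) and Mcub (-1.27), named after their values were seen, were called too. Of 13 erythroid and megakaryocyte markers, 1 was positive and 12 not called, or 2 positive adjusted over the list alone (camera adjusted p = 2.48e-08, adjusted p = 0.0604 with an estimated correlation). Of 15 basophil, eosinophil and mast cell markers, 0 were positive, 0 negative and 15 not called (camera adjusted p = 7.68e-06, adjusted p = 0.296 with an estimated correlation).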

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

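The tests with length and GC trends removed, of sequence shared with other genes and of fewer other-lineage cells in the sort were chosen only after the result was seen, the first with its expected outcome written before it was run.

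The difference between LPS and naive libraries itself differed between populations by interaction terms. It did so for 383 genes between proNeu1 and GMP, 25 between GMP-MoP and proNeu1 and 18 between proNeu2 and proNeu1. When LPS and naive were reassigned within each population, 5, 16 and 17 of 100 splits called as many genes, the real one included. The highest other splits called 649, 298 and 305 genes. Splits that exchange LPS and naive in a single population add both LPS effects in place of subtracting them, so these counts point to the structure of the samples and decide nothing about chance.

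For the 14 comparisons of 2 groups, 3 libraries against 3 give 10 splits, so the share is never under 0.1. In each, 1 of 10 splits called as many genes, the real one. Real count and highest other were 524 and 0 for GMP-MoP against cMoP, 1092 and 1 against MDP, 973 and 3 against GMP, 649 and 11 against proNeu1, and 1391 and 2 against proNeu2. They were 858 and 0 for cMoP against MDP, 1424 and 2 against proNeu1, and 1887 and 0 against proNeu2. For proNeu1 against GMP they were 1417 and 3, and for proNeu2 against proNeu1 153 and 2. With LPS they were 450 and 2 in GMP, 129 and 2 in GMP-MoP, 167 and 2 in proNeu1, and 113 and 0 in proNeu2.

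The first pattern weighed is the 24 genes higher in at least 3 of the 4 LPS comparisons. With length and GC trends removed, 73 of their 84 calls remained, and 19 genes were still higher in at least 3 comparisons, which argues against length or GC bias as the whole cause. Reads shared with pseudogenes or paralogs stay open for the group: its median share of common sequence words was 21.1% against 0.164% for all genes, at percentile 100 of 10000 random lists. The 7 genes picked for a share under 1% (Cebpb, Clu, Mt1, Pmaip1, Dmkn, F7 and Dnmt3l) had at most 0.370%. They were picked by that share, so it is no test of shared reads. Each of the 7 kept at least 3 calls with trends removed, which bears on length and GC bias alone. A biological response to LPS and a batch difference both stay open for the 24, untested.

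The next pattern is lower markers of other blood lineages in LPS GMP. A few genes taking most of the reads is argued against, since 22 of the 23 lower calls of the 3 lists remained with median-of-ratios scaling. Fewer erythroid, megakaryocyte, lymphoid, basophil, eosinophil and mast cells in the LPS GMP sort could also lower them: the medians were -1.59 (interquartile range 1.499), -1.62 (0.85) and, the highest, -0.98 (0.30), with means of naive and LPS GMP of 10146 and 4154 FPKM for Prg2, 3013 and 1123 for Prss34 and 206 and 11.5 for Pf4. The Prg2 call (limma adjusted p = 0.0486) was lost in 6 of 6 leave-one-out runs (0.0712 to 0.122) and with 5 alternatives (0.0532 with the replicate block to 0.144 with a pseudocount of 0.1); that pseudocount also ended the calls of Prss34 (0.0587) and Ear1 (0.0798). In bulk RNA this cannot be told apart from lower expression per cell, and the labels give no sort gates that would exclude such cells. An LPS effect on GMP themselves stays open, untested.

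For the last pattern, higher antibody transcripts in LPS proNeu1, reads of 1 library are argued against: with any 1 of the 6 libraries left out, at least 39 of the 59 antibody genes were still called, and Jchain in 6 of 6 runs. RNA of plasma cells may be a source. Of 12 measured plasma cell genes only 1, Jchain, was called higher, and their median was 0.19, which met the bound written beforehand against this source. That bound was wrong, since 8 of the 12 were already at 10 FPKM or more in naive proNeu1 (Xbp1 118, Creld2 75.1, Edem1 59.4, all in the unfolded protein response list), where a small share of such cells would hardly show. Of the 4 under 10 FPKM, Derl3 was higher (0.69, limma adjusted p = 0.00564) but under the fold threshold. Sdc1 (0.32) and Cd79a (-0.06) were not called, and at levels near 0 this decides little. Plasma cells therefore cannot be told apart from another source, the labels give no gate that would remove them, and an LPS effect stays open, untested.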

How the results depend on the processing

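The recalculations with a mean FPKM of at least 5, voom, length and GC trends removed, a replicate block within the LPS libraries, the LPS libraries numbered 2 left out and immunoglobulin genes left out were tests chosen only after the result was seen.

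The 17 counts of called genes all stayed within 1.5 times with median-of-ratios scaling, a replicate block, the compared groups alone, and trends removed. The planned filter removed no gene, so leaving it out tests nothing. With a pseudocount of 0.1, 10 of 17 stayed within that range, and the others rose: GMP-MoP against cMoP to 845 and against proNeu1 to 1016, proNeu2 against proNeu1 to 567, and LPS in GMP, GMP-MoP, proNeu1 and proNeu2 to 730, 317, 359 and 391. With voom the same comparisons gave 847, 1027, 565, 783, 327, 374 and 414, and the interactions of GMP-MoP and of proNeu2 with proNeu1 8 and 4 (8 of 17 within range). The cause was not tested.

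With a mean FPKM of at least 5 fewer genes are tested, and 2 of 17 counts stayed within range. GMP-MoP gave 309 against cMoP, 630 against MDP, 469 against GMP and 423 against proNeu1; cMoP 505 against MDP, 873 against proNeu1 and 1187 against proNeu2; and proNeu1 714 against GMP. LPS in GMP, GMP-MoP, proNeu1 and proNeu2 gave 200, 66, 76 and 68, and the 3 interactions 155, 5 and 4. Without immunoglobulin genes, again fewer genes, LPS proNeu1 gave 108 and the last 2 interactions 10 and 5.

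These 2 interactions moved elsewhere too: to 41 and 34 with a replicate block within the LPS libraries, and the last to 31 without the LPS libraries numbered 2. With each library left out in turn, 116 of 120 counts stayed within 1.5 times. GMP-MoP minus proNeu1 ranged from 19 to 43 and proNeu2 minus proNeu1 from 13 to 32, with 43 and 30 without LPS proNeu1 replicate 2 and 40 and 32 without LPS proNeu1 replicate 3. The cause was not tested.

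Of 425 gene list tests 183 passed, 182 of them also with a replicate block, but 13 with an estimated correlation, whose cause was not tested. Of 72 recalculated lineage positions 65 stayed within the spread of replicates. The LPS difference on the monocyte set became 0.00824 in GMP-MoP, -0.0183 in proNeu2 and, reversed from 0.0118, -0.0288 in proNeu1 with sets from cMoP against proNeu2 alone. With median-of-ratios scaling it was 0.0299 in proNeu1 and 0.0110 in proNeu2, where a pseudocount of 0.1 gave -0.00587, and on the neutrophil set proNeu2 stood at -0.0265. Genes lower with LPS in both GMP and proNeu2 numbered 2, and 0 with that scaling. The cause was not tested.

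Of 827 called values of named genes, 4 lost their call with the replicate block, 15 with median-of-ratios scaling, 20 with a pseudocount of 0.1, 29 with trends removed, 32 with the compared groups alone and 101 in at least 1 leave-one-out run. With voom 41 of 820 did, and with a mean FPKM of at least 5, 2 of 666. In the LPS comparisons 17 of 180 did without the libraries numbered 2, 1 of 180 with the LPS block and 2 of 177 without immunoglobulin genes. In these runs 0 changed sign. Whether more genes were higher or lower turned under at least 1 alternative for GMP-MoP against cMoP, MDP and proNeu2, the 3 comparisons of cMoP, LPS in proNeu1 and proNeu2, and the interactions of GMP-MoP and proNeu2 with proNeu1. Depth limits genes near an FPKM of 1.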

Other observations

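Same-numbered LPS libraries deviated from their group means together. In 5 of the 6 pairs of LPS groups their correlations across genes were all above 0.1, against 0 of the 39 other pairs. Naive proNeu1 and GMP-MoP came close, at 0.186, 0.375 and 0.0973 (lowest LPS value 0.0875). The labels name no shared mouse, day or batch.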
